A study of Mus musculus with 7 samples.

How the data were processed

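CD45+ cells sorted from mouse cortex were profiled in 7 libraries, 3 of WT 5XFAD and 4 of KΔY75 5XFAD mice, with the 10x Genomics Chromium 3′ v3 kit, per the labels' protocols. Cell Ranger 5.0.0 and the GRCm39 build are named in the submitters' processing notes. The annotation and any filters were not given in the sources used here. The deposited matrices hold raw UMI counts of 21835 genes for 6794880 listed barcodes, cells and empty droplets alike, per the file headers. Gene IDs and symbols came from the files, and 21781 of the IDs matched the GENCODE M21 annotation. That annotation and the gene table supplied with it are of GRCm38.p6, another build, so no coordinates are given and the table served only for names and the order of neighbouring genes. Xist and the T cell receptor and immunoglobulin constant genes are not analysed here. Replicates of a group differed beyond sampling noise in every pair, with chi-square over degrees of freedom of at least 3.86, so no pair was taken for copies of 1 library. Captures of different cells from 1 suspension could differ as much, so this does not show that the libraries are of separate mice.

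Barcodes with at least 1000 UMIs, at least 500 genes and at most 10% mitochondrial UMIs were kept as cells. Scrublet, as implemented in scanpy 1.11.5 with an expected rate of 0.06, was run per library. It marked 36 of 32375 cells, 0.111%, which means that the caller did not work here, and doublets must be taken as still present. The marked cells were left out, and 2 alternatives kept them or removed the highest scores instead. Counts were log-normalized, 2000 variable genes per library were chosen, and cells were clustered with 30 principal components, 15 neighbours and Leiden resolution 1. Clusters were named by markers fixed before the data were examined. A cluster of another class needed at least 3 of its markers raised by at least 4-fold over the other cells, and microglia-like clusters were those with no such class and microglia markers near the level of all cells. These thresholds were set after the files were seen. Clusters with leading genes of another class, or with too few markers, stayed unnamed. So did clusters with median UMIs far below those of their own libraries and no marker of the class among their top 10 genes. Names were rebuilt here and are not the authors' annotation.

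UMI counts were summed per library over microglia-like cells and tested with the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3, with TMM factors, the default low-count filter by group, genotype as the only term, and Benjamini-Hochberg adjustment at 0.05, two-sided. The default prior was used as the stated design names no robust option, but the robust version had been run first and its calls were known when the default was kept. Both are reported. Standard errors are the absolute log2 fold change over the square root of the F statistic. Gene lists were tested with camera of limma 3.58.1. Shares of cells and of UMIs were compared with exact permutation tests over the 35 splits of the 7 libraries, two-sided, where 0.0286 is the smallest p possible, and adjusted over classes or lists. Per-cell shares used cells thinned to 1000 UMIs. Border macrophage-like cells were tested in the same way in libraries with at least 20 cells.

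Named genes were Tyrobp, Trem2, Hcst and Syk whatever they showed, then the 12 largest rises and 12 largest falls among called genes with a mean of at least 50 CPM and no overlap between groups, then up to 4 members of each list with the smallest adjusted p. Predicted genes and clone names were counted but not named. A gene that the rule selects is included in counts but not reported here. Sex-linked genes are given apart: all 7 libraries expressed Ddx3y, Uty, Eif2s3y and Kdm5d. The lists were homeostatic, DAM stage 1 and DAM stage 2 microglia, TREM2-DAP12 signalling, interferon response, MHC class I and class II, cytokines and chemokines, immediate early and heat shock, proliferation, lysosome, lipid handling, cholesterol synthesis, glycolysis and hypoxia, nuclear and mitochondrially encoded oxidative phosphorylation, complement and phagocytic receptors, integrated stress response, NF-kB targets, ribosomal proteins, sex-linked genes, and markers of border macrophages, monocytes, neutrophils, T cells, B cells, neurons, astrocytes, oligodendrocytes, endothelial cells and erythroid cells. T cell, B cell and erythroid markers were too low in microglia for camera, and their UMI shares did not pass the adjustment (exact p = 0.600, 0.114 and 0.800).

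The edgeR step was tested on simulated counts for 11798 genes with 200 changed by 1.5- or 2-fold in the comparison of knock-in with WT microglia. It recovered 100% at each size and made 204 calls, 4 of them false. All simulated genes shared a single coefficient of biological variation, 0.0679, and the changed genes left out the lowest levels. Genes such as Cst7 vary more between the real libraries, so these rates do not measure power or error in the real data. Alternatives covered normalization, filters, the fold threshold, DESeq2 1.42.0, 1 surrogate variable from sva 3.50.0, cell filters, doublets, clustering resolution, thinning, list tests, the replicate number as a block, and each library left out. Depth per library ranged from 13119563 to 57496612 UMIs, so the knock-in values rest on fewer cells and carry more counting error.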

Results

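Single-cell RNA profiles were measured in CD45+ cells, the leukocytes and microglia, sorted from the cortex of perfused C57BL/6 mice aged 6 months. All mice carried 5XFAD, a set of familial Alzheimer's disease mutations that deposits amyloid in the brain. The 3 WT libraries carried the unaltered adaptor protein DAP12, and the 4 KΔY75 libraries came from the DAP12 knock-in line and are called knock-in below. Labels do not say that each library is a separate mouse, so p-values measure only the spread between libraries. Total UMIs per library were 41567306, 57496612 and 57018921 in WT and 15792767, 13119563, 27123926 and 44422976 in the knock-in. After filtering, 32339 cells remained, with 4102, 7258 and 8081 cells per WT library and 1527, 1557, 3469 and 6345 per knock-in library. Median UMIs per cell lay between 5586 and 7531.5. Droplets with under 100 UMIs held 12.1% ± 1.67 (SD, n = 3) of the UMIs in WT and 20.9% ± 6.24 (SD, n = 4) in the knock-in (exact permutation p = 0.0571, two-sided). Microglia-like cells numbered 30288, and 1 of their clusters, of 3000 cells with a median of 0.348 times the UMIs of their own libraries, is called the low-UMI cluster. Without use of clusters, microglia-like cells with under 0.5 times the median UMIs of their library made up 7.29% ± 1.09 of the class in WT and 14.9% ± 7.52 in the knock-in, with every knock-in library above every WT library (exact p = 0.143), a measure added after seeing the data. The gene tests below sum over these cells too, and without the low-UMI cluster edgeR called 181 genes, 151 of them among the 158 given below.

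The first comparison asked what the DAP12 change did to the genes of the receptor complex in microglia-like cells. Levels are given as CPM, the UMI count of a gene per 1000000 UMIs of the microglia-like cells of its library, with library totals scaled by TMM factors. Tyrobp, the gene of DAP12 itself, fell from 3503 ± 306 CPM (SD, n = 3) in WT to 2130 ± 59.9 (n = 4) in the knock-in, a log2 fold change of -0.72 ± 0.06 (SE; edgeR adjusted p = 0.000189). The WT libraries stood at 3219, 3463 and 3827 CPM, and the knock-in libraries at 2194, 2142, 2049 and 2134. Hcst, the gene of the related adaptor DAP10, fell from 54.2 ± 3.34 to 35.2 ± 1.09 CPM, with a log2 fold change of -0.62 (edgeR adjusted p = 0.000382). Its libraries read 53.7, 51.1 and 57.7 CPM in WT and 33.9, 34.8, 36.4 and 35.8 in the knock-in. Trem2, the receptor that signals through DAP12, was at 2834 ± 176 CPM in WT and 2751 ± 120 in the knock-in (log2 fold change -0.04, edgeR adjusted p = 0.729). Its libraries read 2705, 2763 and 3035 CPM in WT and 2799, 2654, 2653 and 2898 in the knock-in. Syk, the kinase recruited by DAP12, was at 120 ± 7.65 CPM in WT and 125 ± 5.30 in the knock-in (log2 fold change 0.07, edgeR adjusted p = 0.558). The altered sequence was not looked for in the 3′ tags, so the counts do not check the mutation itself. Whether the targeting of this gene changes the count of its tags was not tested.

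**Figure D1:**
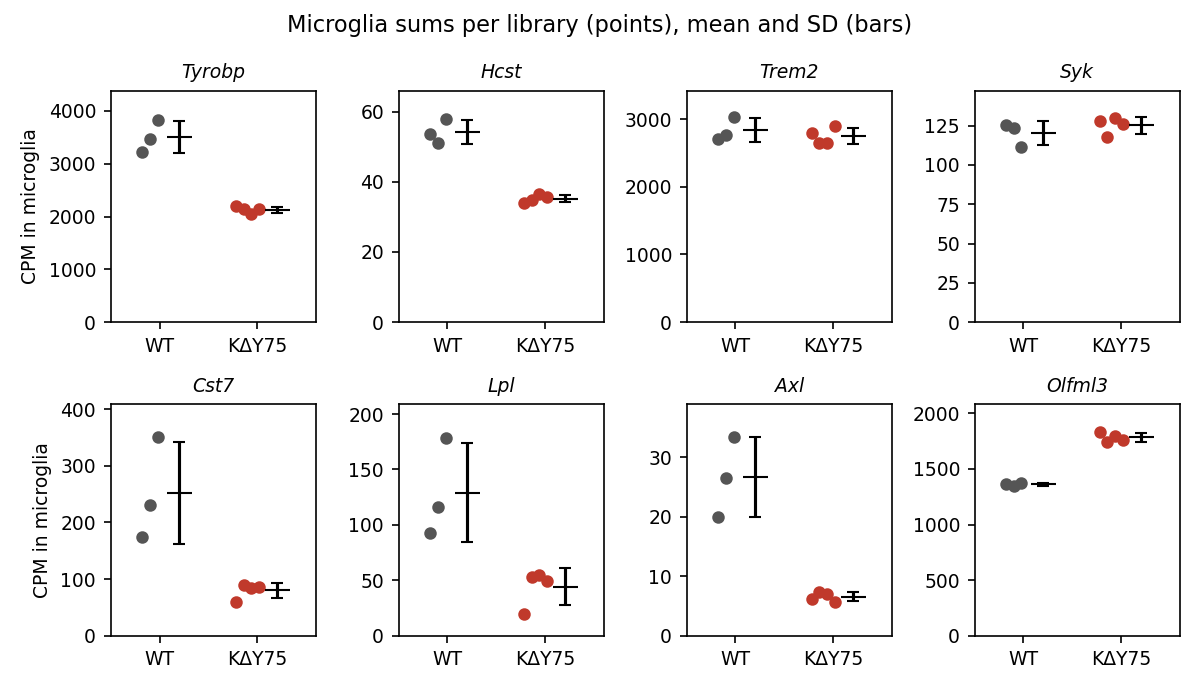
CPM (vertical axis) of 8 genes in microglia-like cells of the 3 WT and 4 KΔY75 libraries. Points are libraries and bars are the mean and SD, and for Tyrobp every knock-in library, at 2194 CPM or below, lies under every WT library, at 3219 or above.

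The second comparison asked which other genes differed between the genotypes in microglia-like cells. The falls among well-expressed genes were led by genes of the disease-associated microglia state. Cst7, which encodes the protease inhibitor cystatin F, fell from 252 ± 89.9 CPM to 79.7 ± 13.3, a log2 fold change of -1.65. Lpl, the gene of lipoprotein lipase, fell from 129 ± 44.6 to 44.1 ± 16.7 CPM, a log2 fold change of -1.52, and Ank, the gene of a membrane protein of pyrophosphate export, fell by 0.94 on the log2 scale. Rises were smaller than the falls of Cst7 and Lpl. They were led by Gmfg, the gene of an actin regulator, which went from 121 ± 5.99 to 233 ± 3.97 CPM, a log2 fold change of 0.94. Further rises on the log2 scale were 0.92 for the sulfotransferase gene Gal3st4, 0.57 for the cyclin gene Ccnd1, 0.55 for the transcription factor gene Bhlhe41, 0.54 for the complement receptor gene C5ar1 and 0.53 for the cholesterol transporter gene Abcg1. Dusp3, Plek, Rin2 and Lars2 rose by 0.53, 0.50, 0.48 and 0.47. Rnaset2b and Rnaset2a rose by 0.61 and 0.59, but they are close copies whose reads can be confused, so each value is uncertain. The other falls were -0.43 for Filip1l, -0.42 for Sult1a1, -0.38 for Marchf1, -0.37 for H2aw, -0.28 for Rassf4, -0.27 for Btg2 and -0.26 for Cd34.

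In all, edgeR called 158 of 11793 tested genes at an adjusted p under 0.05, 87 higher and 71 lower in the knock-in. The balance depended on the setting, with 72 higher and 24 lower at a mean of at least 50 CPM, 70 and 77 with library totals only, 21 and 45 without WT library 1, and 3 and 17 in the test for a change over 1.5-fold. Changes beyond 1.5-fold numbered 22 upward and 49 downward. In each of the 158 genes no knock-in library overlapped a WT library, which held for 15.9% of all tested genes against 5.71% by chance. With robust estimation of the prior, edgeR also called 158 genes, but 132 of them were shared, and Cst7 and Lpl were not among them (edgeR adjusted p = 0.0748 and 0.157). The count fell to 66, 68 and 61 without WT library 1, 2 or 3 and to 64 and 73 without knock-in library 1 or 2, and it rose to 678 without knock-in library 4.

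Several of the named genes lie close to Tyrobp on chromosome 7, by the gene order of the GRCm38.p6 table. Of the 200 tested neighbours, 100 on each side, 15 were called (7.5%), against 142 of 11488 matched genes elsewhere (1.24%). They included Axl, Gmfg, Nccrp1, Mrps12, Ech1, Spred3, Sipa1l3, Zfp30, Alkbh6, Hcst, Sbsn, Lgi4, Fxyd3 and Il4i1, and those outside the naming rule were named after their values were seen. Lgi4 rose from 2.59 ± 0.229 to 22.5 ± 1.64 CPM, while Spred3 fell from 2.33 ± 0.558 to 0.222 ± 0.0934. Without this stretch, edgeR called 130 genes, 73 higher and 57 lower.

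**Figure D2:**
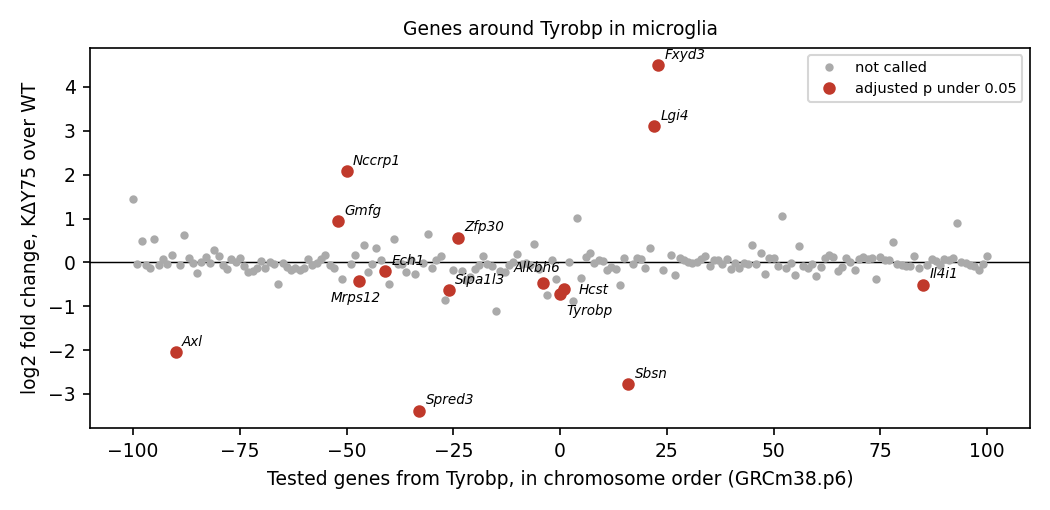
Log2 fold change of KΔY75 over WT in microglia-like cells (vertical axis) for the tested genes around Tyrobp, in chromosome order of the GRCm38.p6 gene table (horizontal axis, in genes). Red points are genes with an edgeR adjusted p under 0.05, Tyrobp itself at 0 among them, and they point both upward and downward. A gene not reported here is not drawn.

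Lists fixed before the data were examined were then compared. Of 28 gene lists tested with limma camera at a preset correlation of 0.01, 11 were called, and none was called with an estimated correlation (smallest adjusted p = 0.374). The list of disease-associated microglia (DAM) stage 2 genes lay lower in the knock-in (camera adjusted p = 1.29e-09, median log2 fold change -0.38), with adjusted p = 0.723 with an estimated correlation. Of its 28 tested members, 8 fell and none rose over all genes tested, while 12 fell and 5 rose adjusted over the list alone. Axl, a receptor tyrosine kinase gene, fell from 26.6 ± 6.76 to 6.59 ± 0.764 CPM, and Ch25h, the gene of cholesterol 25-hydroxylase, fell from 8.40 ± 3.53 to 1.64 ± 0.689. The others that fell were Cst7, Lpl, Ank, Igf1, Itgax and Dkk2, of which the last 2 were named after their values were seen. The 5 that rose over the list alone, also named after their values were seen, were Lgals3, Cd68, Cd9, Ctsl and Apoc1.

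**Figure D3:**
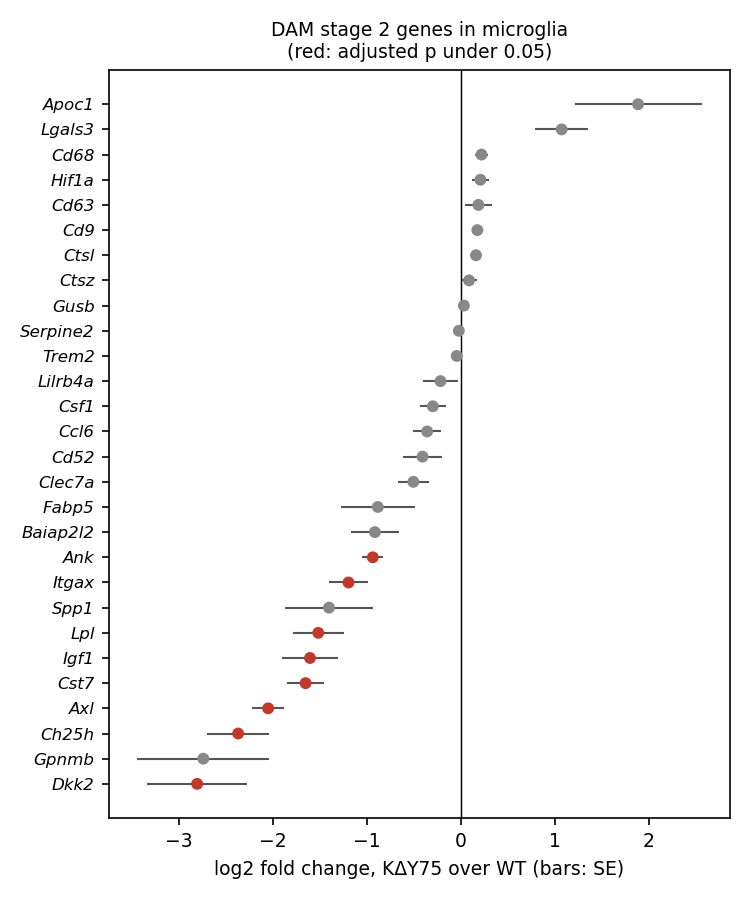
Log2 fold change of KΔY75 over WT (horizontal axis) for the 28 tested DAM stage 2 genes in microglia-like cells, with bars of 1 SE. Red points mark the 8 genes with an edgeR adjusted p under 0.05, all of them lower in the knock-in.

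Antigen presentation genes of MHC class II also lay lower (camera adjusted p = 5.15e-07, but 0.374 as adjusted p with an estimated correlation). Of 7 tested members 3 fell, and 5 fell adjusted over the list alone. Cd74, the gene of the invariant chain, went from 82.6 ± 53.3 to 20.1 ± 7.28 CPM, H2-Ab1 from 28.9 ± 15.6 to 8.87 ± 2.37 and H2-Aa from 17.5 ± 18.7 to 1.03 ± 0.733. WT library 1 held the highest values of all 3 genes, with 144 CPM for Cd74 and with 39.1 CPM for H2-Aa against 5.75 and 7.63 in the other WT libraries. Without it the log2 fold changes went from -2.01 to -1.35 for Cd74, from -1.67 to -1.17 for H2-Ab1 and from -3.94 to -2.59 for H2-Aa, all still called by edgeR. None of the 3 genes was called without knock-in library 1 or 2, with robust empirical Bayes, with 1 surrogate variable, with a 1.5-fold threshold or over all kept cells. Cholesterol synthesis genes lay lower (camera adjusted p = 0.000161, adjusted p = 0.374 with an estimated correlation). Of 20 tested members only Idi1, an isoprenoid enzyme gene, fell, from 7.36 ± 0.108 to 4.90 ± 0.454 CPM, and 5 fell adjusted over the list alone.

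Most other called lists moved by little per gene. Lysosome genes lay higher (camera adjusted p = 3.38e-05, adjusted p = 0.723 with an estimated correlation), with 35 of 36 members positive and a median log2 fold change of 0.09. Only Lipa, the gene of lysosomal acid lipase, rose, from 139 ± 5.63 to 168 ± 12.2 CPM. Nuclear genes of oxidative phosphorylation lay lower (camera adjusted p = 5.56e-05), with 35 of 36 members negative, none called and a median of -0.07. The 13 mitochondrially encoded genes lay higher (camera adjusted p = 0.00457, median 0.09), with none called. Both lists were also called when knock-in libraries 1 to 3 were set against the other 4 (camera adjusted p = 5.04e-05 and 0.00313), a grouping that differs from the real one in 1 library and so cannot tell genotype from it. As UMI shares, nuclear genes held 0.675% in WT and 0.635% in the knock-in, with every knock-in library under every WT library (exact p = 0.0571), while mitochondrially encoded genes held 2.20% and 2.31% (exact p = 0.371). Homeostatic microglia genes lay higher (camera adjusted p = 0.0405), and of 26 members Olfml3 rose, from 1362 ± 12.3 to 1786 ± 39.9 CPM, while 4 rose and 1 fell adjusted over the list alone. Interferon response genes, MHC class I genes and neutrophil markers lay lower (camera adjusted p = 0.0405 each), with no member called. Their median log2 fold changes were -0.15, -0.095 and -1.67, so the neutrophil markers moved far per gene. For each of these lists the adjusted p with an estimated correlation was 0.723 or 0.736.

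The TREM2-DAP12 signalling list lay lower (camera adjusted p = 0.0373), and of 20 members only Tyrobp and Hcst fell (adjusted p = 0.723 with an estimated correlation). Without the 100 tested genes on each side of Tyrobp and without Tyrobp, a setting chosen after seeing the data, the list pointed upward, with camera adjusted p = 0.953. The lipid handling list was not called, although Abcg1 and Lipa rose and Lpl, Ch25h and Fabp3, the gene of a fatty acid carrier, fell. Complement and phagocytic receptors were not called either, with C5ar1 higher and Axl lower, but without the genes near Tyrobp, which include Axl, the list was called upward (camera adjusted p = 0.0344). Single members rose in 3 further lists that were not called, namely Tnfaip2 among NF-kB targets, Stab1 among border macrophage markers and Rps10 among ribosomal proteins. Single members fell in 3 others, namely Igf1 among cytokines and chemokines, Btg2 among immediate early and heat shock genes and Tyrobp in the DAM stage 1 list. Median, mean and test differed in sign for the lipid handling, complement and phagocytic receptor, DAM stage 1 and cytokine lists. The remaining lists, glycolysis and hypoxia, integrated stress response, proliferation, the markers of monocytes, neurons, astrocytes, oligodendrocytes and endothelial cells, and sex-linked genes, were not called and held no called gene.

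As a level that needs no model, the share of microglia UMIs in each list was compared as well. No list of 31 passed the adjustment, but with so few libraries a single list could not pass it whatever its difference. In 3 lists the exact p was 0.0286, the smallest the design allows (adjusted p = 0.295 each), namely TREM2-DAP12 signalling with 0.957% of UMIs in WT and 0.801% in the knock-in, MHC class II with 0.0513% and 0.0380%, and cholesterol synthesis with 0.0248% and 0.0223%. The TREM2-DAP12 list holds Tyrobp itself, whose fall from 3503 to 2130 CPM makes up most of that list's difference. Its share without Tyrobp was not compared. Over 8 alternatives the MHC class II difference ranged from -0.0166 to -0.00798 percentage points. DAM stage 2 genes held 1.18% and 1.17% (exact p = 0.971), so that this share did not follow the lower median of the list. The share is weighted toward abundant members such as Trem2 (2834 CPM in WT), so it can miss falls of genes at low levels.

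The third comparison asked whether microglia-like cells differed in state. Sizes of microglia clusters were not compared, because genes that define the clusters, such as Cst7 and Lpl, differed between the groups. Cells with more DAM stage 2 than homeostatic UMIs, after thinning each cell to 1000 UMIs, made up 0.307% ± 0.0894 (SD, n = 3) of microglia-like cells in WT and 0.138% ± 0.0560 (n = 4) in the knock-in (exact permutation p = 0.0286, two-sided). This division of a range of cells rests on 59 WT and 17 knock-in cells, with 71 cells within 5 UMIs of equality. It reads only the extreme of the cells. Median DAM stage 2 UMIs per thinned cell were 9, 9 and 10 in the WT libraries and 11, 10, 9 and 11 in the knock-in. Homeostatic medians lay between 100 and 107. The typical cell was thus not lower in summed DAM stage 2 UMIs in the knock-in. In this sum, abundant members such as Trem2 (2834 CPM in WT) outweigh members such as Axl (26.6 CPM in WT). It can therefore miss falls of single genes at low levels. Without thinning the shares were 0.229% and 0.113%. Under most other settings the test was not passed, and with at least 30 DAM stage 2 UMIs per cell, a setting chosen after seeing the data, the shares were 3.33% and 2.23% (exact p = 0.114). Cells with at least 3 UMIs of proliferation genes such as Mki67 and Top2a made up 2.47% ± 0.240 in WT and 3.32% ± 1.62 in the knock-in (exact p = 0.543). Knock-in library 2 stood highest, at 5.57%, and without it the difference was 0.0908 percentage points. Without thinning the shares were 60.5% and 56.3%. After thinning, the same threshold was met by 0% of choroid plexus-like, 5.96% of border macrophage-like, 9.95% of T cell-like and 28.1% of neutrophil-like cells. These values cannot tell division of those cells from free RNA. Some small microglia-like clusters had Mki67 and Top2a among their top 10 genes. Free RNA as a source of part of these UMIs was not tested.

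The fourth comparison asked whether the sorted cells differed in composition. Microglia-like cells were 93.8% ± 0.524 of kept cells in WT and 92.9% ± 1.23 in the knock-in (exact p = 0.314). The shares were 89.8% and 82.3% at Leiden resolution 2, 86.2% and 77.0% with a minimum of 500 UMIs and 88.0% and 80.6% with up to 20% mitochondrial UMIs (exact p = 0.0571 each). There unnamed cells held 7.76% and 15.4%, 11.5% and 20.7%, and 9.61% and 16.9%, so the lower shares go with more unnamed cells. Each setting held a large cluster left unnamed by the rule on low UMIs, with no other class as a candidate. These clusters held 2018, 3013 and 2083 cells, with medians of 0.317, 0.285 and 0.319 times the UMIs of their own libraries. At resolution 2 the cells were those of the main setting, so the lower share there comes from naming and not from a loss of microglia. Under the other settings it need not be a loss either. Border macrophage-like cells, led by Pf4 and Mrc1, were 0.366% ± 0.113 and 0.702% ± 0.184 (exact p = 0.0857, adjusted p = 0.707). A cluster with a median of 0.252 times the UMIs of its own libraries gave 55 of these 151 cells, and the shares were 0.284% and 0.342% at Leiden resolution 0.5 (exact p = 0.714) and 0.325% and 0.459% with a minimum of 2000 UMIs (exact p = 0.371). T cell-like cells were 0.593% ± 0.0479 and 0.702% ± 0.265 (exact p = 0.886), and monocyte-like cells 0.564% ± 0.153 and 0.420% ± 0.370 (exact p = 0.571). B cell, neutrophil, natural killer, conventional dendritic and choroid plexus-like cells each averaged under 0.3% of cells in both groups at the main setting. Single libraries reached 0.488% for B cell-like cells (WT library 1) and 0.450% for neutrophil-like cells (knock-in library 2). No class passed the adjustment, but with so few libraries a single class could not pass it whatever its difference. Shares were set by the CD45 sort, the UMI minimum and the naming rules, and 1306 cells stayed unnamed, on average 3.81% in WT and 4.76% in the knock-in. Of these, 1163 formed a single cluster with a median of 0.243 times the UMIs of its own libraries, left unnamed by the same rule on low UMIs. Knock-in library 1 held 0 B cell-like cells among 1527, which allows a share of up to 0.196%, counting error only.

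Border macrophage-like cells were the only other class with at least 20 cells in 2 libraries of each group. The 113 cells of these 4 libraries gave no called gene among 3158 tested by edgeR, with 103 at an unadjusted p under 0.05. DESeq2 called none either, with 16 at an unadjusted p under 0.05. The edgeR count was 33 without knock-in library 3 and 43 without knock-in library 4, where the lone knock-in library was assumed to vary like the WT ones.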

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

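Tests chosen only after the result was seen were those of a strain variant or targeting effect and of cell states for the genes near Tyrobp, of a mislabelled sample, and the count of splits for the genes called. The test of free RNA was added after the split of the knock-in libraries was seen, with its prediction written before its value. A first test of cell states, leaving out cells with more DAM than homeostatic UMIs, removed too few cells to decide anything and was replaced.

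Among the 4 knock-in libraries, a single library lay far from the others in 5 of 75 values tested, and chance alone marks about 1 in 20 groups. The WT libraries were not tested in this way. Cst7 in knock-in library 1 was at 60.1 CPM, with the next library at 84.3. Lpl in the same library was at 19.3 CPM, with the next at 49.7. Cd34 in knock-in library 4 was at 147.0 CPM, with the next at 161. Neuron markers held 0.000528% of microglia UMIs in knock-in library 1, with the next at 0.000417%. Erythroid genes held 0.000800% in knock-in library 3, with the next at 2.26e-05%.

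Genes close to Tyrobp were called more often than genes elsewhere. The block of 200 neighbours held 15 called genes, and the highest of 46 other blocks held 7, so a strain variant or an effect of targeting around the knock-in may account for part of them, a hypothesis found and tested on the same data. The 2 microglia clusters with Cst7 among their top 10 genes, 1 of them the low-UMI cluster, were left out. Outside them the called neighbours kept 0.756 of their median absolute log2 fold change. Other called genes kept 0.741, and the 7 called DAM stage 2 genes not near Tyrobp 0.179. Those 2 ratios compare unlike sets, as some genes, Ch25h and Dkk2 among the 7, were not tested there. The clusters were chosen by Cst7, itself changed and among the 7, which makes 0.179 low by construction. The 0.756 lies between the bounds set for and against a change in cell states. It was moved by Axl, which went from -2.05 to -0.71, and Il4i1 reversed, from -0.51 to 0.47. Every other called neighbour kept its direction and most of its size, such as Lgi4 (3.11 to 3.16), Hcst (-0.62 to -0.61) and Spred3 (-3.38 to -4.08). This argues against a change in cell states, as divided by these clusters, for those neighbours, and leaves it open for Axl and Il4i1. Tyrobp itself, not counted among the neighbours, went from -0.72 to -0.48 outside these clusters and was still called by edgeR. An effect of altered DAP12 on the called neighbours stays open and untested, since the genotype and the surrounding chromosome go together in every library.

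Grouping knock-in library 4 with the WT libraries called 475 genes, more than the 158 of the real grouping, and only 39 genes were shared, but the 3 lists it called (camera adjusted p = 5.04e-05 for nuclear oxidative phosphorylation, 0.00158 for DAM stage 2 and 0.00313 for mitochondrially encoded genes) are among the 11 of the real grouping, in the same directions, as may happen when 6 of 7 libraries keep their place. With each sum thinned to the lowest library total that grouping still called 322 against 205, and without the low-UMI microglia cluster 470 against 181, which argues against total depth and those cells as the whole cause, while the number of microglia per library, 1392 to 7610, was not matched. Droplets under 100 UMIs held 28.6%, 22.9% and 17.6% of UMIs in knock-in libraries 1 to 3. In knock-in library 4 they held 14.4% and in WT at most 14.0%, which follows this grouping. But the genes higher in libraries 1 to 3 had a median log2 ratio of free-droplet to microglia CPM of -0.000349, against 0.101 over all tested genes. They were not richer in free droplets than other genes, which argues against free RNA as the whole cause. The limit is that the microglia sums that chose these genes also enter the ratio, which can lower it. Tyrobp in knock-in library 4 was at 2134 CPM, near the 2128 of the other knock-in libraries, which argues against a mislabelled sample. Knock-in libraries 1 to 3 also kept the fewest cells, 1527, 1557 and 3469, against at least 4102 in every other library. Cell yield thus follows this grouping too, and its effect was not tested. What sets the 3 libraries apart stays open, and a biological difference between mice was not tested.

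The lower DAM stage 2 list was set against depth and cell quality. On thinned sums the median log2 fold change of the list was -0.36, and without the low-UMI cluster -0.43, against -0.38, which argues against library totals and the low-UMI cells as the whole cause, with cell numbers not matched. The median absolute log2 fold change of its 7 called members not near Tyrobp was 1.61. Outside the 2 clusters with Cst7 among their top 10 genes it was 0.29, a median without Ch25h and Dkk2, which were not tested there. With the clusters chosen by 1 of these genes, this cannot tell a change in cell states from a change within cells. An effect of the DAP12 change on these genes remains a hypothesis.

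Splits of the 7 libraries were used to ask whether chance can be excluded. For the 158 genes called, 2 of 35 splits called as many, so chance is not excluded at 0.05. The other was knock-in libraries 1 to 3 against the rest, with 475, which differs from the real split only in knock-in library 4. Setting knock-in libraries 1, 2 and 4 against the rest called 4 genes, and every remaining split called 0. For the 11 lists called by camera, 14 of 35 splits called as many, the highest other 19, so chance is not excluded. For the camera p of the DAM stage 2 list, 4.62e-11, only the real split of the 35 gave a value as small, under 0.05 for this list taken alone. But this list also had the smallest camera p of the 28 lists. With no adjustment for the 28 lists, chance is not excluded. The margin is narrow, since the 4 splits that join WT libraries 2 and 3 with a knock-in library gave 2.25e-10 to 9.08e-09 in the same direction, and the list is not called with an estimated correlation (adjusted p = 0.723) or with fry (adjusted p = 0.283).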

How the results depend on the processing

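The count of 158 genes called in microglia became 374 without a filter on low counts, 96 with a mean of at least 50 CPM, 20 for a change over 1.5-fold, 43 over all kept cells and 465 with DESeq2, and ranged from 61 to 678 when single libraries were left out. The 1.5-fold test is stricter by construction, and for the others the cause was not tested. It stayed within 1.5 times of 158 in 15 of 27 alternatives. The alternatives chosen after seeing the data were the robust prior, removal of the highest Scrublet scores, the sums without the low-UMI cluster, without the clusters with Cst7 among their top 10 genes and without the genes near Tyrobp, and the threshold of 30 DAM stage 2 UMIs. The 25 genes of the named set that were called kept their direction in all 624 values and their call in 507, and 2 of them, including Gmfg, kept it throughout. Trem2, not called, ranged from -0.0759 to 0.00879 in log2 fold change when libraries were left out and changed sign only without WT library 3. The 11 lists called became 7 over all kept cells, 7 on thinned sums, 0 with an estimated correlation and 0 with fry, and ranged from 5 to 12 when libraries were left out. The DAM stage 2 list had an adjusted p of 0.723 with an estimated correlation and 0.283 with fry, in a range from 2.53e-25 to 0.723. The TREM2-DAP12 list turned upward without the genes near Tyrobp, at 0.953. Labels do not say whether replicate numbers pair the libraries. Same-number correlations of deviations were 0.184, the highest of any WT and knock-in pair, -0.00928 and -0.0692, too few to decide it. The replicate block gave 620 genes and 6 lists. Knock-in library 4 has no WT library of its number, so under the block it adds nothing to the genotype contrast. Leaving it out alone gave 678 genes. The difference in DAM-over-homeostatic share kept its direction and lost its call at -0.0905 percentage points with 2000 UMIs, -0.119 with at most 5% mitochondrial UMIs, -0.165 at Leiden resolution 2, -0.0432 with 1.5 times as many UMIs, -0.176 without the low-UMI cluster and -1.10 at 30 UMIs, and from -0.205 to -0.119 when libraries were left out, where fewer libraries limit the exact p. The cycling share reversed to -4.23 percentage points without thinning, where deeper cells reach 3 UMIs more easily. Border macrophage-like cells gave 0 to 43 called genes when libraries were left out. A sex covariate was not run because all libraries carried Y-linked transcripts, and no class had 50 cells in enough libraries.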

Other observations

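Microglia outside the 2 clusters with Cst7 among their top 10 genes were looked at apart, leaving out 5834 of 30288 cells, a choice made after seeing the data. Of these, 3000 were the cells of the low-UMI cluster, so that the setting also removes those, and as Cst7 itself changed, the cells left out depend on the difference under test. There edgeR called 123 genes, 93 higher and 30 lower in the knock-in, and 91 of them were also among the 158 called in all microglia-like cells.

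Cells of other types were scarce in the sort. Classes other than microglia and border macrophages were too few for a test of genes in both groups. T cell-like cells reached 20 in 3 WT libraries but in only 1 knock-in library, and monocyte-like cells in 2 WT libraries and 0 knock-in libraries.

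Apoe, a lipid carrier gene of the DAM stage 1 list, varied within both groups. It stood at 1105, 1157 and 2017 CPM in WT and at 2269, 1096, 564 and 2016 in the knock-in, with an edgeR adjusted p of 0.961.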
